A study of Oryza sativa with 4 samples.

How the data were processed

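Leaf RNA of rice seedlings (Oryza sativa, genotype Dongjin, 7 days old, 16 h light and 8 h dark at 23 °C) was profiled in 4 libraries, 2 irrigated with buffer (1 mM HCl) and 2 with 5 mM CysNO, per the labels' protocols. Poly(A) RNA was fragmented, primed with random hexamers, made into TruSeq libraries and read as 100 bp pairs on an Illumina HiSeq instrument, per the labels' protocols. The protocol speaks of leaf samples in triplicate, and each group has 2 libraries here. The authors deposited 1 FPKM value per locus and library, per the file headers, with the chromosome, start, end and strand of each of 57995 loci and a symbol for 617 of them. The submitters' processing notes name Bowtie 0.12.2 and the build mm8, which is a mouse build and does not match rice loci. The build behind the coordinates, the counting program, the annotation release and any filter are not given in the sources used here, so whether reads shared by similar or overlapping loci were divided, and whether strand was used, is unknown.

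The deposited FPKM values give no read counts, so no count test and no counting interval was used, and the depth is unknown. Relative depth was estimated from 642 loci above a small positive floor in every library and under 0.3 FPKM. It was taken as the most frequent log2 ratio to control 1 (kernel density, bandwidth 0.03). Between 30068 and 32002 loci per library are listed at 0. Genes a leaf uses, such as the chloroplast psbA and psaA and the mitochondrial cox1, are listed at 0 in all 4 libraries, so a value of 0 can be a failed estimate. Loci listed at 0 in a group are therefore given per library, with no mean and no fold. Chloroplast and mitochondrial RNA is mostly not polyadenylated, which a poly(A) library under-represents.

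Loci with at least 1 FPKM in at least 2 of the 4 libraries (21123) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, CysNO against control, two-sided. Benjamini-Hochberg adjustment was made over all tested loci, with a threshold of 0.05. The model has 2 residual and 5.36 prior degrees of freedom. A permutation test of 2 against 2 libraries could not go below p = 0.333 and was not used. Data were simulated for the 21123 loci with 200 of them changed, independent errors and variances drawn from the prior that limma fitted. On them the test found 0% of 50 genes changed 2-fold and 60% of those changed 4-fold. It found 96% of those changed 8-fold and 98% of those changed 16-fold. Of its 134 calls 5.22% were false, and it made 0 calls in data where no gene was changed. Errors shared within a library were not simulated, and far more loci were called in the real data. The shares found and false need not hold there.

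The choice of groups, tests, 46 gene lists, 22 panel loci and the rule for named genes was fixed before the data were examined. The lists were patterns to be matched on gene descriptions. The files hold symbols and no descriptions, so the patterns could be matched on symbols alone, and only 2 lists then had 3 or more tested members, the bHLH genes and the auxin list, whose matches are SAUR genes. Diterpenoid phytoalexin synthesis was fixed as 8 loci, of which CYP76M7 was left out of the main list test because the gene table puts that name on another chromosome. The list with all 8 is given beside it. The other lists were assembled from the deposited symbols after the files had been opened. The WRKY and shoot meristem lists matched 1 tested gene each and are described by gene. Lists of at least 3 tested loci, 20 in all, were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, whose p asks only whether a list's own genes move one way on balance. The rule named the 12 loci with the largest positive and the 12 with the largest negative log2 fold change among called loci with a symbol, a mean of at least 1 FPKM and no overlap between groups (only 5 fell), up to 3 called members of each list (or the most abundant member where none was called), and the whole panel. For lack of descriptions, a symbol in the files was required in their place.

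Names come from the files or, for panel and DREB1 loci, from a gene table of the rice assembly ASM3414082v1, which does not hold the files' locus names and was used only for names and neighbours. It has 170 of the 484 nuclear symbols on the same chromosome and 8 only on another. Of the 22 panel names, 14 are on the chromosome of their locus, 11 of them with a span within 10% of that in the files (WRKY76, PBZ1 and DREB2A were not), and 8 are not in the table. All coordinates are those of the files.

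The alternatives were quantile normalization, median centring, a pseudocount of 0.1, no filter on low values, a filter of 5 FPKM, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and the 2 other list tests. After the data were seen, 4 more were added, leaving out loci listed at 0 in any library, leaving out loci above 1000 FPKM and rescaling the rest to equal sums, limma without the trend, and the phytoalexin list with all 8 loci. Alternatives that need counts, also chosen before the data were examined, do not apply to FPKM and were not run.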

Results

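The question put to these plants was which leaf transcripts respond to a nitric oxide donor. Rice seedlings of the genotype Dongjin were grown for 7 days, then irrigated with 5 mM S-nitrosocysteine (CysNO) or with buffer (1 mM HCl). CysNO is a small S-nitrosothiol (a thiol whose sulfur carries nitric oxide) that releases nitric oxide and transfers it to protein cysteines. No library was treated with cysteine alone, so an effect of nitric oxide cannot be told apart from one of the rest of the molecule. The labels give 1 mM HCl for the control only, so an effect of the buffer cannot be told apart either. Leaf poly(A) RNA was sequenced as 100 bp read pairs, in 2 control and 2 CysNO libraries. Nothing in the labels says that the libraries of a group came from separate plants, so the p-values below measure only the spread between these samples, which may be technical. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 57995 loci. Each library summed to between 687469 and 732401 FPKM and had between 20444 and 20770 loci at 1 FPKM or more. Read counts and total depth are unknown. In 642 loci of low expression the most frequent ratio between libraries put the relative depth, with control 1 set to 1, at 1.07 for control 2, 0.825 for CysNO 1 and 1.08 for CysNO 2. Across the tested loci, which are not independent replicates, log2 values correlated at 0.9405 between the controls, at 0.9543 between the CysNO libraries and at 0.8668 to 0.9082 between groups.

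Of 6 panel genes of nitric oxide and nitrate metabolism, HB1, HB2 and NR2 rose after CysNO, NIA1 and GSNOR did not pass the test and NIA2 was not tested. Of those that rose, NR2 alone also passed with both median centring and quantile normalization. HB1 and HB2 are hemoglobin genes, whose products belong to a class that converts nitric oxide to nitrate. HB1 (LOC_Os03g13140) went from 9.81 ± 9.17 FPKM (SD, n = 2) in control to 71.02 ± 28.1 (SD, n = 2) in CysNO, a log2 fold change of 3.0 with a standard error of 0.62 and an adjusted p of 0.0421 in limma's moderated test. Its log2 fold change was 2.0 without control 1 and 4.0 without control 2. HB2 (LOC_Os03g12510) went from 11.2 ± 5.41 FPKM to 49.2 ± 2.03 (SD, n = 2), a log2 fold change of 2.12 ± 0.35 (SE; limma, adjusted p = 0.0205). The locus taken as the nitrate reductase gene NR2 (LOC_Os02g53130) went from 0.485 ± 0.164 FPKM to 20.5 ± 3.90 (SD, n = 2), a log2 fold change of 3.85 ± 0.30 (SE; limma, adjusted p = 0.00207). NIA1, another nitrate reductase gene, had 4.53 ± 0.498 and 10.7 ± 3.21 FPKM (SD, n = 2) and did not pass (limma, adjusted p = 0.125). NIA2 was too low to test, with 1.92 and 0.336 FPKM in the controls and 0.128 and 0.451 in CysNO. GSNOR, for the enzyme that breaks down S-nitrosoglutathione, stood at 105 ± 9.80 FPKM in control and 104 ± 19.1 in CysNO (SD, n = 2), with a log2 fold change of -0.02 ± 0.28 (SE; limma, adjusted p = 0.983). These loci belong to a panel of 22 fixed before the data were examined. Of its 21 tested loci, 4 rose and 0 fell over all loci tested, and 9 rose and 2 fell when adjusted over the list alone. The 5 that passed only there and had higher values in CysNO were NIA1, APX2, WRKY53, DREB2A and sgr, and the 2 with lower values were CATA and DREB1A. For NR2, NIA2, GSNOR, CATC, WRKY45, WRKY53, PR1A and PR1B the pairing of locus and name rests on general knowledge, since neither the files nor the gene table used here gives it.

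The rest of the panel covered oxidant scavenging, defence and stress. WRKY62 (LOC_Os09g25070), a defence-related transcription factor gene, was the other panel member that rose, from 27.0 ± 0.0869 FPKM to 107 ± 15.6 (SD, n = 2), a log2 fold change of 1.94 ± 0.26 (SE; limma, adjusted p = 0.0108). Its neighbour WRKY76 had a log2 fold change of -0.52 ± 0.25 (SE; limma, adjusted p = 0.345). WRKY53 had 448 ± 1.39 FPKM in control and 1149 ± 109 in CysNO (SD, n = 2) and did not pass over all loci (limma, adjusted p = 0.0862), while it passed when adjusted over the list alone (0.0184). WRKY45 did not pass (log2 fold change 0.38; limma, adjusted p = 0.611). The catalase genes CATA, CATB and CATC had log2 fold changes of -0.88, 0.07 and -1.18, and the ascorbate peroxidase genes APX1 and APX2 had 0.76 and 1.13, with limma adjusted p from 0.0901 to 0.941. The defence markers PR1A, PR1B and PBZ1 had log2 fold changes of 0.35, -0.26 and -0.81, with standard errors of 0.50 to 0.61 (limma, adjusted p from 0.583 to 0.89). AOS2, of jasmonate synthesis, did not pass (log2 fold change -0.41; limma, adjusted p = 0.661). The stay-green gene sgr had 44.2 ± 4.91 FPKM in control and 86.4 ± 6.41 in CysNO (SD, n = 2; limma, adjusted p = 0.0952). Of the DREB genes, which encode stress-responsive transcription factors, DREB1A had a log2 fold change of -0.74 (limma, adjusted p = 0.198) and DREB2A one of 1.18 (limma, adjusted p = 0.055).

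DREB1B and DREB1H, the neighbours of DREB1A on chromosome 9, fell. DREB1B (LOC_Os09g35010, bases 20394743 to 20395724) went from 203 ± 67.2 FPKM to 19.1 ± 5.70 (SD, n = 2), a log2 fold change of -3.33 ± 0.34 (SE; limma, adjusted p = 0.00516). DREB1H (LOC_Os09g35020, bases 20398853 to 20399782) went from 135 ± 31.6 FPKM to 14.5 ± 1.84 (SD, n = 2), a log2 fold change of -3.12 ± 0.28 (SE; limma, adjusted p = 0.00312). Both were singled out after their values were seen, and their names come from their place between RAD and DREB1A in the gene table. The span of DREB1B is 982 bp in the files and 984 bp in the table, and that of DREB1H is 930 bp against 1071 bp, outside the 10% allowed for panel names, so the name DREB1H is less certain. How the authors' counting divided reads between such similar neighbours is not given in the sources used here.

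Several members of auxin-related gene families rose, although no such family passed as a whole with all libraries. Of those named here, only saur23 and iaa9 also passed with both median centring and quantile normalization. Of the 20 tested SAUR genes (small auxin up RNA genes, a list fixed before the data were examined), 5 rose and 0 fell over all loci, and 7 rose and 3 fell when adjusted over the list alone. saur23 (LOC_Os04g56690, chromosome 4, bases 33619219 to 33620361) rose the most of the loci with a symbol and controls above 0, from 1.19 ± 0.683 FPKM to 73.8 ± 16.6 (SD, n = 2), a log2 fold change of 5.11 ± 0.33 (SE; limma, adjusted p = 0.00148). SAUR3, saur15 and saur16 also rose, each with 1 control library listed at 0. SAUR3 read 0 and 1.97 FPKM in the controls against 8.51 and 10.9 in CysNO, saur15 read 0 and 1.5 against 5.39 and 12.1, and saur16 read 1.01 and 0 against 6.51 and 4.84. Without control 1, the library at 0, the log2 fold change of SAUR3 was 1.84 (limma, adjusted p = 0.0394) and that of saur15 was 1.87 (limma, adjusted p = 0.0745). The list's median log2 fold change was -0.20 and its mean 0.55, so they differ in sign, and camera gave the direction up (adjusted p = 0.395 over 20 lists). Without control 2, where SAUR3 and saur15 have only a control listed at 0, the median of the SAUR list was 0.14. The Aux/IAA, GH3, cytokinin oxidase, response regulator, gibberellin and shikimate lists were put together from the deposited symbols after the files had been opened. Of 27 tested Aux/IAA genes, which encode repressors of auxin response, 2 rose and 0 fell over all loci, and 4 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.255). iaa9 went from 0.562 ± 0.165 FPKM to 12.02 ± 6.56 (SD, n = 2; limma, adjusted p = 0.0116), and iaa20 was listed at 0 in both controls and at 1.84 and 1.99 FPKM in CysNO. Of 9 tested GH3 genes, a family in which some products, but not all, join amino acids to auxin, 2 rose and 0 fell (camera, adjusted p = 0.255). gh3.8 went from 8.61 ± 3.88 to 56.7 ± 23.6 FPKM (SD, n = 2), and gh3.5 from 18.8 ± 1.58 to 45.3 ± 2.82 (SD, n = 2). Whether the products of these 2 genes act on auxin was not tested. Without control 2 the median log2 fold change of the GH3 list was 0.89, against 0.19 with all libraries. Of the fits with a library left out, the SAUR and GH3 lists passed camera in that fit only. It takes the spread of the lone control from the CysNO libraries.

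Of 3 tested genes for cytokinin oxidases, which break down cytokinin, ckx5 and ckx4 rose and 0 fell, and the list did not pass with all libraries (camera, adjusted p = 0.188 with all libraries, 0.0371 without control 2 and 0.0459 without CysNO 1). ckx5 went from 11.9 ± 0.991 to 64.5 ± 20.6 FPKM (SD, n = 2; log2 fold change 2.31 ± 0.30, SE; limma, adjusted p = 0.01), and ckx4 from 3.66 ± 0.852 to 16.8 ± 5.24 (SD, n = 2; limma, adjusted p = 0.0237). ckx3 had a log2 fold change of -0.47 ± 0.32 (SE; limma, adjusted p = 0.533). None of the 8 tested type-A response regulators, which cytokinin induces, passed (median log2 fold change -0.49; camera, adjusted p = 0.255), and rr6, the most abundant, had a log2 fold change of 0.21 (limma, adjusted p = 0.822). Of 13 tested gibberellin genes, 1 fell and 0 rose over all loci, and 2 fell and 2 rose when adjusted over the list alone (median log2 fold change 0.04, mean -0.09; camera direction down, adjusted p = 0.762). The gene that fell over all loci was ga20ox4, for a gibberellin 20-oxidase, which went from 8.11 ± 4.41 to 1.16 ± 0.122 FPKM (SD, n = 2; limma, adjusted p = 0.0381).

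The shikimate pathway, which makes the precursors of aromatic amino acids, was the 1 list of 20 to pass camera with the preset correlation (median log2 fold change 1.24, adjusted p = 0.00626), and it was assembled only after the files had been opened. The call was lost with an estimated correlation (adjusted p = 0.883) and without CysNO 2 (adjusted p = 0.0563). Of its 6 tested genes 3 rose and 0 fell over all loci, and 4 rose and 0 fell when adjusted over the list alone. None of the 3 passed with both median centring and quantile normalization. DAHPS1, for the first enzyme of the pathway, went from 66.9 ± 23.9 to 267 ± 87.8 FPKM (SD, n = 2; log2 fold change 1.99 ± 0.37, SE; limma, adjusted p = 0.0314). Sk2, a shikimate kinase gene, went from 18.9 ± 10.3 to 78.9 ± 10.2 (SD, n = 2; limma, adjusted p = 0.03), and CS1, for chorismate synthase, from 23.3 ± 1.77 to 61.1 ± 1.84 (SD, n = 2; limma, adjusted p = 0.03). The phenylalanine ammonia-lyase gene ZB8, whose product takes phenylalanine into phenylpropanoid synthesis, rose from 65.5 ± 27.2 to 314 ± 0.348 FPKM (SD, n = 2; log2 fold change 2.30 ± 0.35, SE; limma, adjusted p = 0.016). PAL5, another gene of that enzyme and singled out after its values were seen, rose from 59.0 ± 14.9 to 240 ± 50.5 FPKM (SD, n = 2; limma, adjusted p = 0.0173). Of the 8 loci of diterpenoid phytoalexin synthesis fixed before the data were examined, 0 passed over all loci, and 1 had a lower value that passed when adjusted over the list alone (median log2 fold change -0.21; camera, adjusted p = 0.326). That locus, LOC_Os02g36110, had 102 ± 22.8 FPKM in control and 45.0 ± 4.28 in CysNO (SD, n = 2; log2 fold change -1.15 ± 0.28, SE; limma, adjusted p = 0.0715 over all loci and 0.0323 over the list alone). It had been taken as CYP76M7, a name that the gene table puts on another chromosome. In the 7 other loci, 0 passed over all loci and 0 when adjusted over the list alone (median log2 fold change -0.11; camera, adjusted p = 0.728). CPS2, of the same list, had 87.0 ± 1.32 FPKM in control and 70.8 ± 18.0 in CysNO (SD, n = 2; limma, adjusted p = 0.67).

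**Figure D1:**
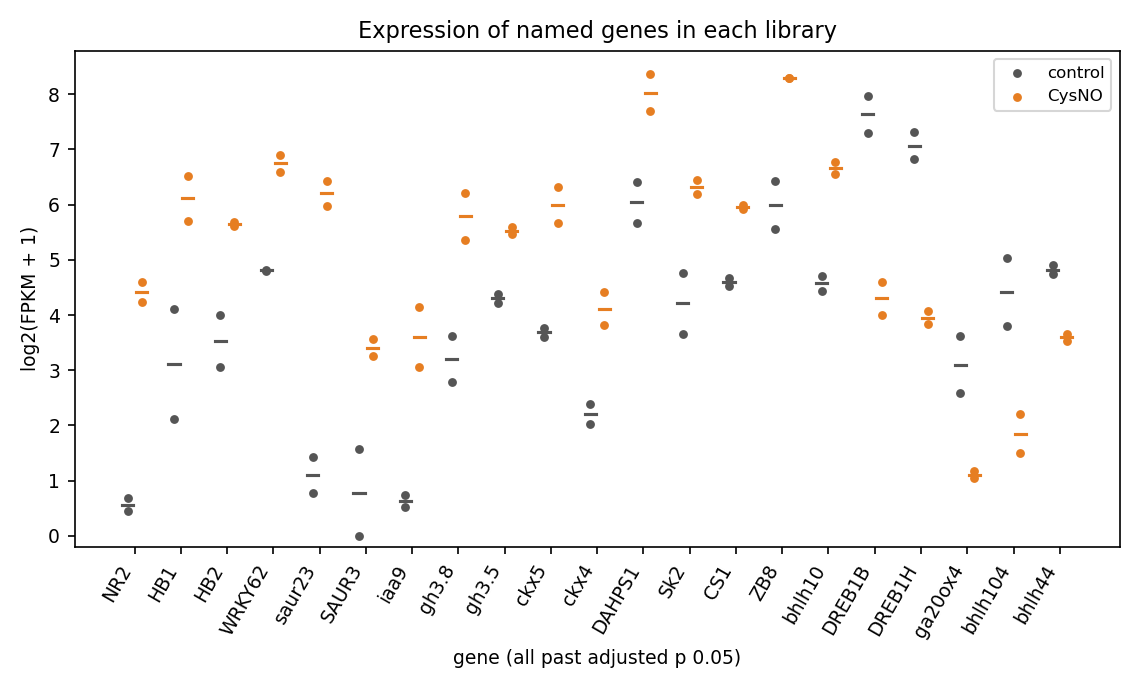
Expression of 21 named genes in each library as log2(FPKM + 1) on the vertical axis, with 1 point per library (2 control in grey, 2 CysNO in orange) and a bar at the group mean. All 21 passed limma's adjusted p threshold of 0.05. For each of them both CysNO points lie on the same side of both control points, which the naming rule had required of some of them.

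Among transcription factors, the bHLH genes went both ways. Of 121 tested bHLH genes, a list fixed before the data were examined, 6 rose and 3 fell over all loci, and 12 rose and 4 fell when adjusted over the list alone. The median log2 fold change was -0.01, the mean 0.04 and camera's adjusted p 0.762 (direction up). bhlh10 (LOC_Os01g50940) rose from 23.0 ± 3.11 to 100.2 ± 10.8 FPKM (SD, n = 2; log2 fold change 2.08 ± 0.26, SE; limma, adjusted p = 0.00903), and bhlh36 read 0 and 0.185 FPKM in the controls against 12.5 and 6.14 in CysNO. bhlh104 fell from 22.4 ± 13.4 to 2.71 ± 1.25 FPKM (SD, n = 2; log2 fold change -2.57 ± 0.46, SE, -1.95 without control 1 and -3.19 without control 2; limma, adjusted p = 0.0279), bhlh102 from 9.11 ± 0.733 to 2.93 ± 0.0644 (SD, n = 2) and bhlh44 from 27.4 ± 2.07 to 11.1 ± 0.734 (SD, n = 2). Other named genes that rose were rugt-5, from 7.88 ± 3.59 to 65.1 ± 10.01 FPKM (SD, n = 2; limma, adjusted p = 0.00708), and GGPR2, from 30.1 ± 16.8 to 138 ± 20.1 (SD, n = 2; limma, adjusted p = 0.0264). CHL fell from 12.2 ± 5.58 to 2.70 ± 0.721 FPKM (SD, n = 2; limma, adjusted p = 0.0463).

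**Figure D2:**
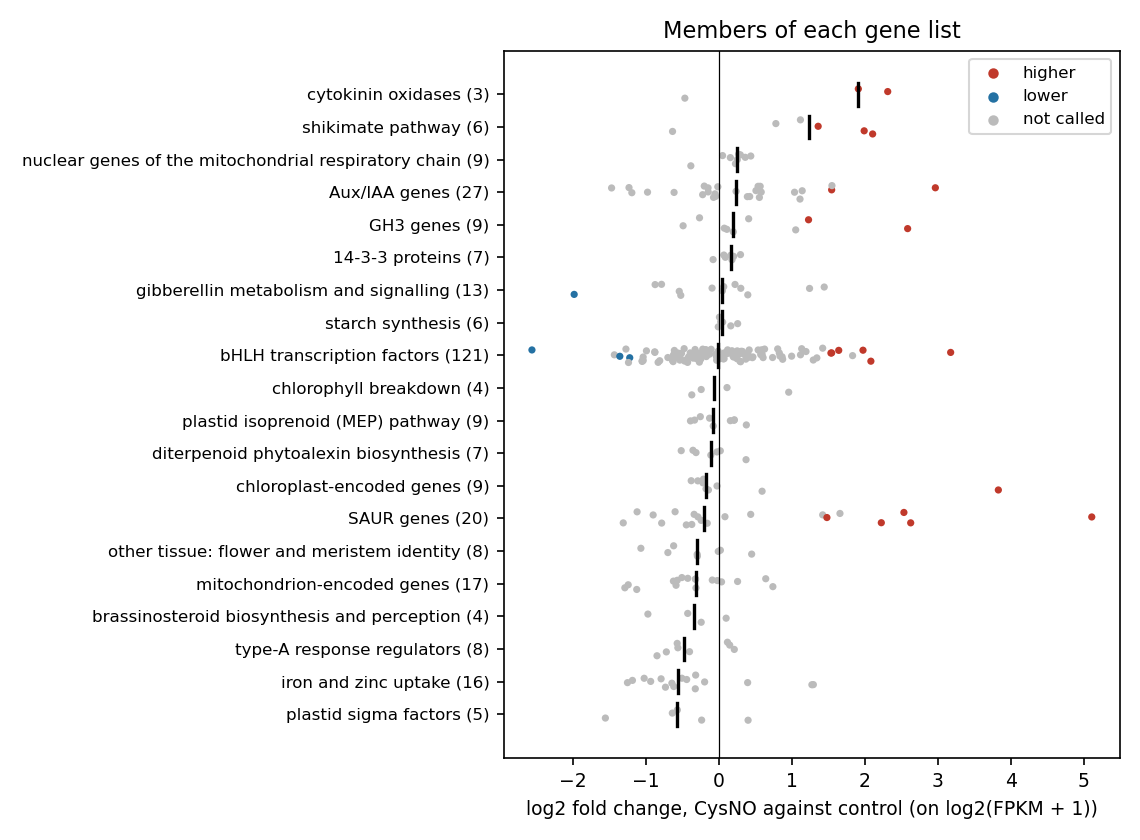
Log2 fold change, CysNO against control, of each tested member of the 20 gene lists (horizontal axis, on log2(FPKM + 1)), with the number of tested members in brackets, the list median as a black bar and members past limma's adjusted p threshold of 0.05 in red (higher) or blue (lower). Of the 20 tested SAUR genes, 5 are red, and the shikimate list has 3 red members of 6 and a median of 1.24.

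Over all 21123 tested loci, 691 were higher and 202 lower in CysNO at a limma adjusted p under 0.05, so 77.4% of the 893 calls were higher. The median log2 fold change was 2.00 among the higher and -1.70 among the lower calls, on the log2(FPKM + 1) scale, which understates the change of low loci. Of the 397 tested loci with a symbol in the files, 25 rose and 5 fell. Of the loci without a symbol and with no library at 0, LOC_Os03g61500 had the largest log2 fold change and LOC_Os04g48350 the most negative. LOC_Os03g61500 went from 0.438 ± 0.0516 to 151.5 ± 60.98 FPKM (SD, n = 2; 6.67 ± 0.34, SE; limma, adjusted p = 0.000712). LOC_Os04g48350 went from 26.4 ± 2.72 to 0.418 ± 0.0571 FPKM (SD, n = 2; -4.27 ± 0.28, SE; limma, adjusted p = 0.00168). LOC_Os01g48349 also passed, listed at 0 in both controls and at 4332 and 3616 FPKM in CysNO. So did LOC_Os05g04720, at 14.4 and 11.8 FPKM in the controls and listed at 0 in both CysNO libraries. These 4 loci were picked after their values were seen. The groups did not overlap at 46.4% of the tested loci, where chance gives 33.3%. The number of calls depended on the scaling, with 381 higher and 68 lower with median centring. It also depended on the libraries kept. Almost all calls were lost without either CysNO library, and most were kept without either control. A lone library gives no spread of its own, so the variance then came from the other group alone. Limma's prior degrees of freedom were 2.82 without CysNO 1, 2.86 without CysNO 2, 9.22 without control 1 and 9.32 without control 2. How far the calls rest on any 1 library cannot be read from these fits. Of the 35 named genes that passed, 15 also passed with both median centring and quantile normalization, among them saur23, NR2, WRKY62, iaa9, ckx5, bhlh10, rugt-5, DREB1B and DREB1H, while 18 passed with neither. The log2 fold changes of the 35 moved by at most 0.005 with median centring and 0.214 with quantile normalization. Limma's prior degrees of freedom fell from 5.36 to 3.35 and 3.54. The 18 were HB1, HB2, ZB8, PAL5, SAUR3, saur15, saur16, iaa20, gh3.8, gh3.5, ckx4, ga20ox4, DAHPS1, Sk2, GGPR2, CHL, bhlh104 and bhlh102, and CS1 was lost with quantile normalization and bhlh44 with median centring.

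**Figure D3:**
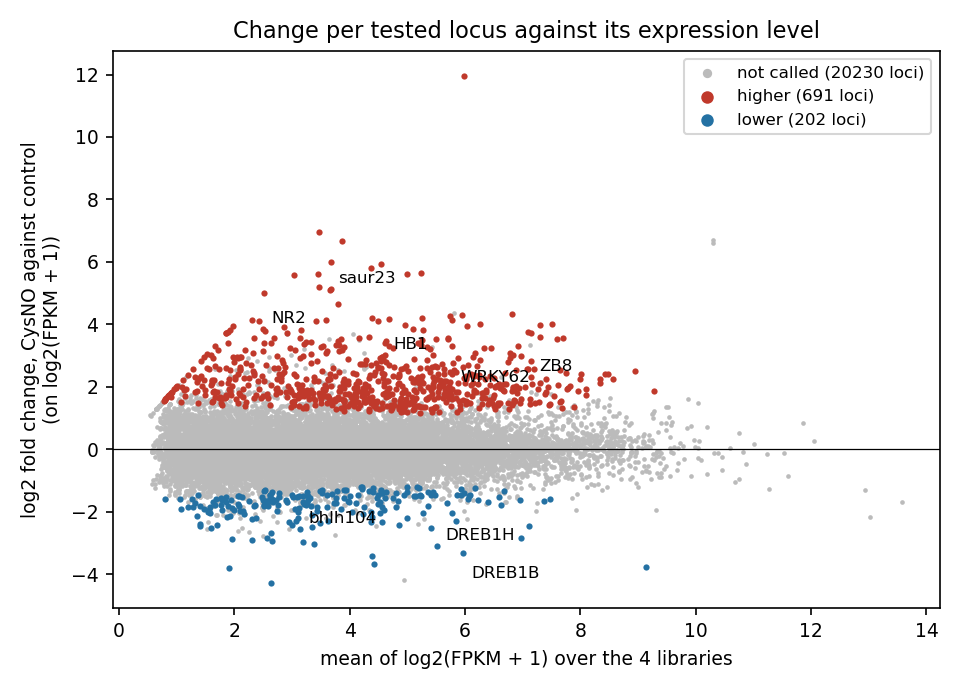
Log2 fold change, CysNO against control, on log2(FPKM + 1) (vertical axis) against the mean log2(FPKM + 1) of the 4 libraries (horizontal axis), with 1 point per tested locus. The 691 loci called higher are red and the 202 called lower are blue, at a limma adjusted p under 0.05, and 8 of the named genes are marked.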

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

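The alternatives that leave out loci at 0, leave out loci above 1000 FPKM, drop the variance trend or keep all 8 phytoalexin loci were chosen after the data were seen. In each alternative, 0 of the tested main calls changed sign. Against 691 higher and 202 lower calls, there were 393 and 87 with quantile normalization (480 of the 893 main calls kept), 381 and 68 with median centring (449 kept), 326 and 90 without loci above 1000 FPKM (416 of 889 kept, with the median of all loci at -0.12), 172 and 14 at an adjusted p under 0.01, and 2 and 0 with no filter (4162 at an unadjusted p under 0.05), where the prior degrees of freedom fell from 5.36 to 2.20. The counts stayed within 1.5 times with a pseudocount of 0.1 (578 and 136), a filter of 5 FPKM (738 and 246), loci at 0 left out (714 and 264) and no trend (673 and 170). A fold limit of 2 could remove no call (691 and 202). The smallest called log2 fold change was 1.145 among the higher and -1.205 among the lower. With 1 library left out the lone library of its group was assumed to vary like the other group, and the calls ranged from 0 (without CysNO 1) to 816 higher (without control 2) and from 0 (without either CysNO library) to 484 lower (without control 2). The labels do not say that replicate numbers pair the samples, and the correlation of same-numbered deviations was -0.186; with the replicate number as a block, 53 were higher and 2 lower, a fit with fewer residual degrees of freedom. The count of lists past camera's threshold was 1 in the scaling, filter, pseudocount and block fits and with all 8 phytoalexin loci, 0 with an estimated correlation and 0 with fry, and 2 to 5 with a library left out, among them SAUR genes, GH3 genes and cytokinin oxidases without control 2 (adjusted p = 0.0371 for each). Of the 35 named genes that passed, 16 passed with median centring, 16 with quantile normalization, 1 with no filter, 6 with the block, 24 without control 1, 29 without control 2, 0 without CysNO 1 and 1 without CysNO 2. The causes of the other changes were not tested. Depth is unknown, so no limit of detection can be set. The DESeq2, edgeR and recovered-read alternatives were not run, since they need counts.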

Other observations

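The lists not described above had no member past the threshold, with 1 exception, and camera's adjusted p was 0.255 or more for each. All 16 tested genes of iron and zinc uptake missed it (13 with a negative log2 fold change, median -0.57; camera, adjusted p = 0.255), and the most abundant, NAS2, read 993 and 479 FPKM in the controls and 227 and 754 in CysNO. That list passed camera without control 2 (median -0.96, adjusted p = 0.0371) and without CysNO 2 (median -1.19, adjusted p = 0.00384). None of 9 genes of the plastid isoprenoid pathway passed (median -0.08, DXS3 log2 fold change -0.26). The same held for 6 starch genes (median 0.04, APL3 0.16) and 7 genes for 14-3-3 proteins (median 0.16, GF14b 0.20). Nor did any of 5 plastid sigma factor genes (median -0.57, Sig5 -1.56, Sig2B 0.40) or of 4 brassinosteroid genes (median -0.34, D61 -0.43). The 4 genes listed for chlorophyll breakdown, NYC1, PaO, NOL1 and sgr, did not pass either (median -0.07, mean 0.11). CHL, which fell, was not in that list, and its symbol alone does not show whether it belongs there. Adjusted over the list alone, Sig5 passed with a lower value (adjusted p = 0.0227, against 0.0765 over all loci) and sgr, of chlorophyll breakdown, with a higher one (0.028, against 0.0952). Nuclear genes of the mitochondrial respiratory chain had 0 of 9 past the threshold (median 0.25; atpB2 0.43), and mitochondrion-encoded loci 0 of 17 (median -0.32; LOC_Osm1g00540 -0.09), a list that passed camera without control 1 (median -0.65, adjusted p = 0.00121) and without CysNO 2 (median -0.48, adjusted p = 0.0423). Of 9 tested chloroplast-encoded loci, rps16, for a ribosomal protein, was the exception, listed at 0 in both controls and at 20.3 and 8.50 FPKM in CysNO. That list's median was -0.18, and its 8 other loci had a median of -0.20 and a mean of -0.11. Without CysNO 1 the median turned to 0.71 and the list passed camera (adjusted p = 0.00143).

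As to tissue make-up, 0 of 8 tested flower and meristem identity genes passed (median -0.30; camera, adjusted p = 0.326), with MADS22 at 46.4 ± 1.53 and 46.4 ± 8.88 FPKM (SD, n = 2) and the meristem gene OSH1 at 5.08 ± 2.27 and 1.88 ± 1.01 (SD, n = 2; limma, adjusted p = 0.214). Of 5 seed and germination genes only AMY2A was high enough to test (3.31 ± 0.514 and 1.32 ± 0.421 FPKM, SD, n = 2; limma, adjusted p = 0.192), and no root marker pattern matched a symbol. WRKY71 had 528 ± 134 FPKM in control and 1062 ± 109 in CysNO (SD, n = 2; limma, adjusted p = 0.211). Control 2 differed from the other libraries in its most abundant loci. The 10 largest took 16.6% of its sum against 11.5% in control 1, 7.48% in CysNO 1 and 10.2% in CysNO 2.

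Of the tests in the next 3 paragraphs, the count of loci at 0 in 1 library of a group was chosen after its result was seen, and rescaling without abundant loci was added as an alternative after the data were seen. LOC_Os01g48349 was listed at 0 in both controls and at 4332 and 3616 FPKM in CysNO, and no other locus went from 0 to 100 FPKM or more between groups in both libraries. An assignment of its reads to an overlapping locus goes against the table, since 0% of such loci (0 of 1) overlap another locus, where 3.02% of all loci do. Failed estimates written as 0 stay open, since 9 loci were at 0 in 1 library and at 100 FPKM or more in its fellow, 8 of them in the controls. Of these, LOC_Os09g00999, LOC_Os09g01000 and LOC_Os12g38650 were above 100 FPKM in every library but 1. The rest were at 0 in more than 1 library, so the count of 9 mixes lone zeros with other patterns, such as lone high values. A response to CysNO, which may be the origin of the pattern, stays open beside failed estimates.

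Called loci lay next to each other more often than shuffled calls did. Among 11697 neighbouring tested pairs, 44 were called in the same direction (41 both higher, 3 both lower) and 2 in opposite directions, where shuffles gave a median of 7 opposite pairs. Overlapping loci that share reads do not account for it, since 43 pairs remained without overlaps, against a median of 13 and a highest value of 27 in 10000 shuffles. A shared expression level does not either, since shuffles within 20 bins of mean expression gave a median of 14 and at most 31 against 44. Reads shared between similar neighbours, such as DREB1B with DREB1H and saur15 with saur16, were not tested and stay open, and co-regulation of neighbouring genes by CysNO is a hypothesis that these data may hold.

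Higher calls outnumbered lower ones, at 77.4%. A few loci taking much of the total do not alone account for this majority. With loci above 1000 FPKM left out and the rest rescaled, 78.4% were higher. That fit made fewer calls, and the share was also higher among the fewer calls at an adjusted p under 0.01 (92.5%). Whether abundant loci raised the share in part is therefore not settled. Compression of low values by the pseudocount does not alone account for the majority either, since 85.3% of the 484 calls at a mean of 20 FPKM or more were higher. Without control 2 the calls went to 816 higher and 484 lower, a share of 62.8%. The scaling assumes that total RNA per leaf was alike, which these values cannot show. A response to CysNO made up more of gains than of losses is a hypothesis that stays open beside that.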
